A study of Mus musculus with 8 samples.

How the data were processed

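Total RNA was extracted with TRIzol from bone marrow cells of 8 mice on the B6D2F1 background, 4 of them PlGF transgenic and 4 wild type, and biotin-labelled cRNA was hybridised to Affymetrix expression arrays, per the labels' protocols. The series' design text names 4 mice in each group. The sex, age and housing of the mice, the construct of the transgene, scan dates and array batches are not given in the sources used here.

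The deposited table holds 1 log2 value per probe set and array, for 22690 probe sets on 8 arrays. Per the submitters' processing notes, the values were made with RMA, a method that summarises the probes of a probe set after background correction and quantile normalization between arrays in its standard form. The version of RMA, the kind of its background step and any settings are not given in the sources used here. That the scale is log2 was read from the values, which ran from 0.55 to 13.46 with array medians between 3.64 and 3.69. The array medians lay close together, so the values measure each transcript relative to the rest of the marrow RNA and not per cell. No detection call accompanied the values, so low values were kept, and the level is given for some of the genes that lie low.

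Samples were assigned to groups from the condition label of each sample. No pair of columns held identical values, and the correlations between arrays ran from 0.983 to 0.995. The 64 Affymetrix control probe sets were left out of the tests, which left 22626. Gene symbols came from a platform annotation table, updated through gene identifiers with a RefSeq gene table of assembly GRCm38.p6. Of all probe sets 20393 had 1 symbol, 691 had several and 1606 had none, and gene identifiers of 20364 of the 1-symbol probe sets were found in the RefSeq table. Genes were named only from probe sets with 1 symbol. Some listed markers, such as Cd19 and Gypa, matched no named probe set and are unnamed here. The order of genes along the chromosomes, used for windows and blocks of neighbouring genes, came from the RefSeq table. No coordinates are printed, since no genome build was named for the array table.

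Transgenic and wild type arrays were compared on the log2 values as deposited with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates), and p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets with a threshold of 0.05. Folds are powers of 2 of the log2 differences. Single values per array, such as list means and control ratios, were compared with exact two-sided permutation tests over all 70 arrangements of 4 against 4, whose smallest p is 0.0286.

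Gene lists for marrow cell types, stress responses, metabolism, sex-linked transcripts and strain polymorphisms, 35 lists with 701 entries, were written from textbook knowledge before the data were examined, as were most tests and alternatives. Of the entries 605 matched a measured gene, 6 of them through a synonym, and 96 did not. Each of 12393 genes was represented by its probe set with the highest mean over all 8 arrays. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, two-sided and adjusted over the 35 lists. Camera with a correlation estimated per list and fry, a rotation test of whether the genes of a list move on balance in 1 direction, were alternatives. Members were also tested with adjustment over the list alone.

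The genes named in the text were chosen by a rule set in advance. They are Pgf and the members of the VEGF family list. In each direction the largest changes past the threshold were to be named, and, where fewer than 8 passed, the genes with the smallest unadjusted p up to 8, stated not to pass. In each list up to 4 members with the smallest p were named. Genes outside this rule are said to be chosen after their values were seen.

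The alternatives were arrays centred on their medians, a further quantile normalization, leaving out probe sets with a mean below the median, eBayes with trend and robust variance, array weights, the replicate number as a block, an unmoderated equal-variance test, 1 probe set per gene, a 1.5-fold minimum, an adjusted p of 0.1, the mean of all probe sets of a gene, a background restricted to brighter genes, and leaving out each mouse in turn. After seeing the data, 3 more were added: an indicator of Xist signal as a covariate, leaving out both arrays with Xist signal, and the Gapdh 3' minus 5' control difference as a covariate.

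The fit was tested on simulated data for the 4 against 4 comparison over 22626 probe sets. Of 100 probe sets changed 2-fold it recovered 85% on independent values and 84% on the real arrays with group means removed, and of 100 changed by 2 log2 units 98% and 97%, with 6 and 0 false calls. With group means removed every unchanged probe set differed by exactly 0, so those 0 false calls were fixed in advance. Recovery there holds no sampling error of the difference, and both sets of 100 were changed in the same run. Of 10 simulated lists of 20 genes shifted by 0.5 log2 units camera called 10, and of 10 lists not shifted it called 0, in values without correlation between genes. Correlations estimated for real lists reached 0.66 for mature B cell and MHC class II, 0.51 for late neutrophil and 0.73 for late erythroid genes, so this simulation does not cover such lists.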

Results

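Bone marrow cells from 8 mice on the B6D2F1 background, a cross of the C57BL/6 and DBA/2 inbred strains, were profiled on Affymetrix expression arrays, with 1 array per mouse. The series' design text describes 4 of the mice as transgenic mice overexpressing placenta growth factor (PlGF, encoded by Pgf), a secreted ligand of the VEGF family that binds the receptor Flt1 and the neuropilins. The other 4 mice were wild type. The deposited log2 values ran from 0.55 to 13.46, the array medians lay between 3.64 and 3.69, and correlations between arrays lay between 0.983 and 0.995. The number of arrays limits the precision of every value. The comparison asked which marrow transcripts differ between PlGF transgenic and wild type mice, and all differences below are transgenic minus wild type on the log2 scale.

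The Pgf transcript was not measurably higher in the transgenic marrow. The Pgf probe set averaged 2.22 ± 0.12 (SD, n = 4) in transgenic and 2.10 ± 0.23 (SD, n = 4) in wild type mice, a difference of 0.12 (SE 0.12, limma adjusted p = 0.767). Its mean exceeded that of 32.4% of all probe sets, which is low on these arrays. Whether the probe set lies within the part of the transcript that the transgene carries, and in which tissue the transgene is active, is not given in the sources used here, so this value does not check the labels. Without both arrays that carry Xist signal, an alternative chosen after seeing the data, the Pgf difference was -0.015, and without wild type mouse 2 it was 0.02.

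None of the 10 measured members of the VEGF family and its receptors passed the test. The member with the smallest p was Vegfa, the main angiogenic ligand of the family, at 4.33 ± 0.28 in transgenic against 3.85 ± 0.15 in wild type mice (SD, n = 4), 1.40-fold higher with an unadjusted limma p of 0.0074 and an adjusted p of 0.394. The other Vegfa probe set gave a difference of 0.12. Flt1, the signalling receptor for PlGF, differed by 0.15 on its brightest probe set and by 0.34 and -0.0065 on the others. Differences were 0.13 for the co-receptor Nrp1, 0.14 for Nrp2, 0.14 for Vegfd, -0.09 for Vegfc, -0.20 for Vegfb, -0.17 for Kdr and -0.04 for Flt4, with adjusted p-values from 0.608 to 0.913. Other Vegfd probe sets went the other way, by -0.05 and -0.24. The list as a whole had a mean difference of 0.07 (camera adjusted p = 0.339).

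No probe set passed an adjusted p of 0.05 in either direction among the 22626 tested with limma, and the lowest adjusted p was 0.233. At an unadjusted p under 0.05 limma gave 1203 probe sets higher and 1128 lower in transgenic marrow, together 2331 or 10.3%, where 1131 would stand at 5%. That count was 1408 without wild type mouse 3, 3419 without wild type mouse 1, 3369 with array weights and 1534 with the Gapdh 3' minus 5' control difference as a covariate, added after seeing the data. An unmoderated equal-variance test also called 0 after adjustment, with 2092 at an unadjusted p under 0.05. The values of both groups did not overlap at all for 1242 probe sets, 5.49%, where chance gives 2.86% on average for 4 against 4. Such counts differ widely between ways of dividing the arrays. Of the 35 splits into 4 and 4, the real one included, 4 gave as many as 2331 at an unadjusted p under 0.05. The highest other gave 4221. The count without overlap was not run over the splits, so chance is not excluded for either count. A simulated doubling of 100 probe sets on these arrays, with group means removed, was recovered for 84%. Another 100 were changed by 2 log2 units in the same run. That setting leaves out the sampling error of the difference, so 84% is not the power of this comparison.

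The genes with the smallest unadjusted p in each direction are described here as measured, and none of the 16 passed the adjusted test. Higher in all 4 transgenic mice was Acod1, which makes itaconate in activated myeloid cells, at 7.11 ± 0.18 against 5.74 ± 0.35 (SD, n = 4), 2.59-fold with an SE of 0.17 log2 units (limma adjusted p = 0.233). With array weights this gene alone passed, at an adjusted p of 0.0496, while its adjusted p was 0.233 as deposited. Fosl1, a subunit of the AP-1 transcription factor, stood 3.14-fold higher at 4.71 ± 0.57 against 3.06 ± 0.40, and its other probe set 1.22-fold higher. The scavenger receptor gene Olr1 was 1.69-fold higher, the endotoxin-induced Litaf 1.62-fold, Ccdc88c 1.52-fold and Dock9 1.51-fold. That Dock9 probe set lay at a low level, 2.52 against 1.93. Brighter Dock9 probe sets differed by 0.33 and 0.73, with groups that overlapped. Osbpl9 stood 2.01-fold higher on 1 probe set, where its other probe sets differed by 0.08, 0.08 and 0.37, and the splicing factor gene Rbm39 2.48-fold higher on 1 of 9 probe sets whose differences ran from 0.09 to 1.31.

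On the lower side, Klk1, a tissue kallikrein, averaged 3.40 ± 0.70 in transgenic and 5.49 ± 0.61 in wild type marrow (SD, n = 4), 4.24-fold lower with an SE of 0.38 log2 units (limma adjusted p = 0.384). A second Klk1 probe set differed by -1.90 and the third by -0.33, and kallikreins form a family of close paralogs whose transcripts these probe sets could share. Ccr3, the eotaxin receptor of eosinophils, was 1.63-fold lower at 2.57 ± 0.06 against 3.27 ± 0.15. The adhesion gene Cdh1 was 1.68-fold lower, Socs2, a feedback inhibitor of cytokine signalling, 1.55-fold, B3galnt1 1.55-fold, Klhl7 1.51-fold, the mitochondrial ribosomal gene Mrpl52 1.46-fold and the F-box gene Skp2 1.40-fold. Levels were low for Socs2, at 2.05 against 2.68, and for B3galnt1, at 1.64 against 2.27. The other Skp2 probe sets differed by -0.05 to -0.33.

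**Figure D1:**
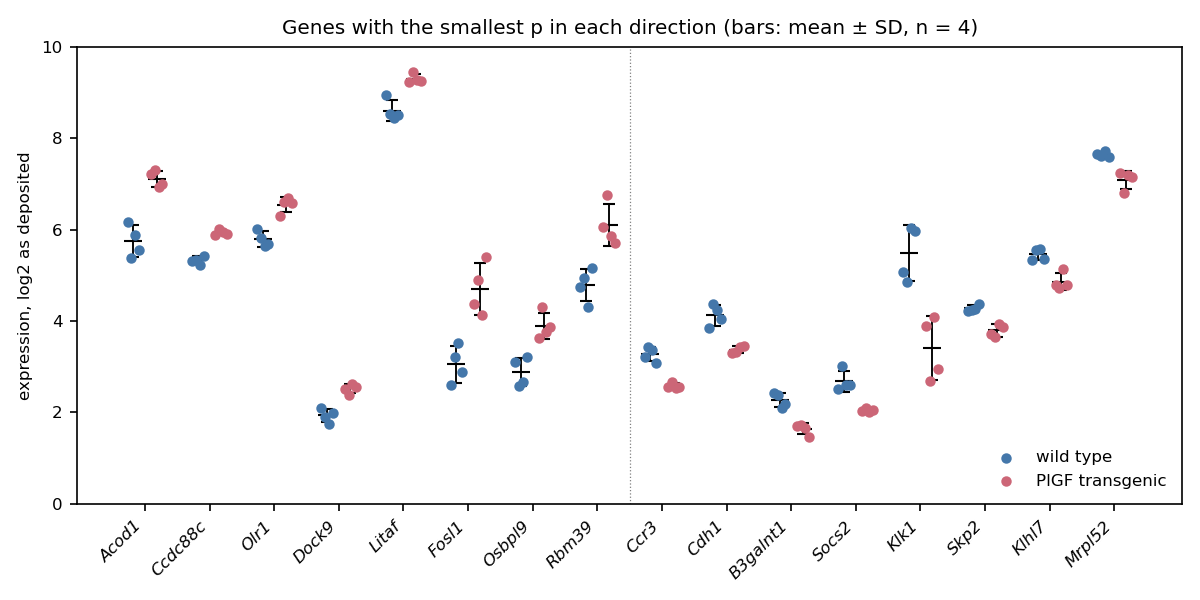
Deposited log2 expression of the 8 genes with the smallest unadjusted p in each direction, higher in transgenic on the left and lower on the right, with 1 point per mouse (wild type blue, PlGF transgenic red) and bars for mean ± SD (n = 4). The groups do not overlap for any gene shown, for example Acod1 (7.11 against 5.74 on average) and Klk1 (3.40 against 5.49). Their choice by small p on the same arrays made this likely in advance, and no gene passed the adjusted test.

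Gene lists fixed in advance passed a test where single genes did not. Of 35 lists of cell types and pathways, 13 passed an adjusted p of 0.05 with camera at its preset correlation between genes, 4 of them higher and 9 lower in transgenic marrow. None of the 13 held with a correlation estimated from the arrays (adjusted p = 0.792 for each) or with fry, whose lowest adjusted p was 0.419. The count of lists was 8 without transgenic mouse 2 and 7 without transgenic mouse 4. Over all probe sets 0 list members passed.

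B lymphocyte genes had the largest mean shifts of the 35 lists. The mature B cell and MHC class II list was 1.34-fold lower on average, with 17 of 19 measured members lower (camera adjusted p = 3.46e-07, and adjusted p = 0.792 with an estimated correlation). No member passed over all probe sets, and 9 passed as lower adjusted over the list alone. Among them were H2-Oa at 4.71 ± 0.28 against 5.44 ± 0.23 and H2-Ab1 at 7.23 ± 0.24 against 7.90 ± 0.25 (SD, n = 4), which encode class II chains found in B cells and other antigen-presenting cells. H2-Eb1 differed by -0.60 and Fcer2a, the low-affinity IgE receptor of mature B cells, by -0.76. The B cell precursor list was 1.35-fold lower, with 18 of 21 members lower (camera adjusted p = 1.31e-05, and adjusted p = 0.792 with an estimated correlation). Adjusted over the list alone, 2 of its members passed as lower. Fcrla stood at 5.22 ± 0.33 against 6.16 ± 0.41, Vpreb3 differed by -0.66, Cd79b of the B cell receptor by -0.74 and the recombinase gene Rag2 by -0.67. Array means of neither list separated the groups by exact permutation (two-sided p = 0.143 and 0.0857, where the smallest possible is 0.0286). Wild type mouse 1 lay among the transgenic mice at -0.25 and -0.23, and for the mature B cell list transgenic mouse 2, at 0.24, lay above wild type mouse 4, at 0.21.

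The T and NK cell list was 1.18-fold lower, with 21 of 26 members lower (camera adjusted p = 0.0045, and adjusted p = 0.792 with an estimated correlation). No member passed, over all probe sets or adjusted over the list alone. The chemokine receptor Cxcr6 differed by -0.37, the kinase Txk by -0.31, the T cell receptor chain Cd3e by -0.35 and Cd27 by -0.29. Levels were low for Cxcr6, at 1.77 against 2.15, Txk, at 1.62 against 1.94, and Cd27, at 2.80 against 3.09. The exact permutation p of the array means was 0.371. Its mean of -0.24 was -0.12 without transgenic mouse 4, -0.11 without wild type mouse 3 and -0.14 without wild type mouse 4, each of which ended the call, and -0.39 without wild type mouse 1, -0.39 without both Xist arrays and -0.40 with array weights. The call was also lost in both settings restricted to brighter probe sets (-0.25 and -0.29).

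Neutrophil genes shifted the other way. The late neutrophil list, made of granule and mature neutrophil genes, was 1.28-fold higher, with 21 of 22 members higher (camera adjusted p = 1.25e-05, and adjusted p = 0.792 with an estimated correlation). No member passed, over all probe sets or adjusted over the list alone. The gelatinase Mmp9 averaged 10.42 ± 0.23 against 9.77 ± 0.51 and lactoferrin, Ltf, 12.18 ± 0.11 against 11.87 ± 0.21 (SD, n = 4), while Trem1 differed by 0.65 and Padi4 by 0.59. With the Gapdh 3' minus 5' difference as a covariate, added after seeing the data, the list's mean of 0.35 was 0.23. Its array means overlapped (two-sided exact permutation p = 0.143), with wild type mouse 1 at 0.29, above the transgenic mice at 0.06 to 0.27. The early granulocyte granule list was 1.18-fold higher with all 9 measured members higher (camera adjusted p = 0.028, and adjusted p = 0.792 with an estimated correlation). Its examples Gstm1, Elane, Prtn3 and Mpo differed by 0.46, 0.37, 0.35 and 0.19, and none passed. Its array means overlapped too (exact p = 0.314), with wild type mouse 1 at 0.36. This call was lost without transgenic mouse 2 (mean 0.19), transgenic mouse 4 (0.13), wild type mouse 2 (0.15) or wild type mouse 3 (0.17), with the Gapdh covariate (0.17), without both Xist arrays (0.11) and in both settings restricted to brighter probe sets (0.24 in each), and the mean was 0.36 without transgenic mouse 1 and 0.40 without wild type mouse 1.

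Macrophage and eosinophil genes stood lower. The resident marrow macrophage list was 1.31-fold lower, with 15 of 16 members lower (camera adjusted p = 0.00062, and adjusted p = 0.792 with an estimated correlation). The adhesion molecule Vcam1 averaged 7.52 ± 0.25 against 8.01 ± 0.31 (SD, n = 4), the mannose receptor Mrc1 differed by -0.73, the complement gene C1qa by -0.55 and the hemoglobin scavenger receptor Cd163 by -0.70, and no member passed. With the Gapdh covariate the list's mean of -0.39 was -0.23. Its array means overlapped (two-sided exact permutation p = 0.114), with wild type mouse 1 at -0.32, below 3 of the 4 transgenic mice, and the other wild type mice at 0.17 to 0.48. The eosinophil list was 1.24-fold lower, with 5 of 6 members lower (camera adjusted p = 0.0067, and adjusted p = 0.792 with an estimated correlation). Ccr3 was its 1 member that passed adjusted over the list alone. The granule proteins Prg3 and Prg2 differed by -0.44 and -0.16. The interleukin receptor Il5ra, at a low level of 2.24 against 2.66, differed by -0.42. The exact p of the list's array means was 0.0857. The call was lost without transgenic mouse 1 (mean -0.23), without both Xist arrays (-0.22) and in the settings restricted to brighter probe sets (-0.18).

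Controls of RNA integrity and the overall position of the arrays did not separate the groups by exact permutation. With 4 against 4 this does not show equal RNA quality. The Gapdh control signal at the 3' end exceeded that at the 5' end by 0.78 ± 0.26 in transgenic and 1.03 ± 0.24 in wild type marrow (SD, n = 4, two-sided exact permutation p = 0.171). It was 0.60 to 0.69 in transgenic mice 1 to 3, below all wild type mice at 0.70 to 1.24, and 1.16 in transgenic mouse 4. The same 3' minus 5' difference for Actb was 0.72 ± 0.11 against 0.84 ± 0.08 (exact p = 0.171). The 18S control averaged 10.83 ± 0.38 against 11.18 ± 0.49 (exact p = 0.286). On the first principal component, with 33.9% of the variance, wild type mouse 1 and transgenic mouse 4 both stood at 28.5, the other wild type mice between -29.1 and -11.2 and the other transgenic mice between -11.5 and 14.9. Group means on this component were 8.88 ± 16.96 in transgenic and -8.88 ± 26.06 in wild type mice (SD, n = 4, exact p = 0.343). No batch was named in the labels used here.

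**Figure D2:**
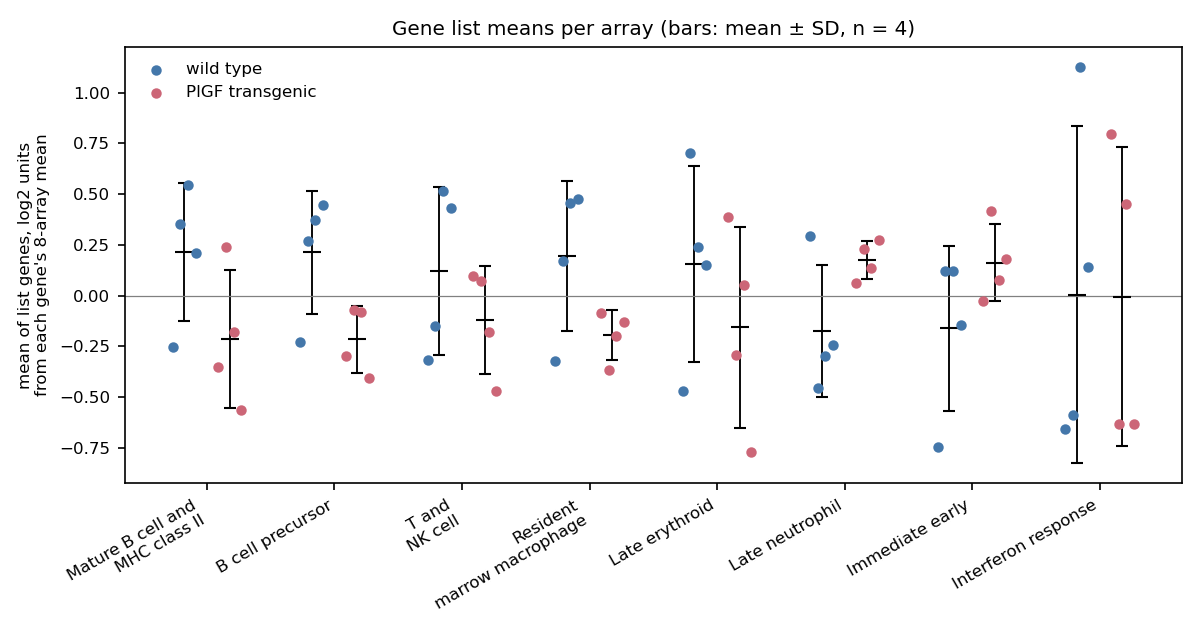
Mean of the list genes per mouse, in log2 units from each gene's mean over the 8 arrays, for 8 gene lists, with 1 point per mouse (wild type blue, PlGF transgenic red) and bars for mean ± SD (n = 4). For mature B cell and MHC class II genes 3 wild type mice lay between 0.21 and 0.55 and wild type mouse 1 at -0.25, and the interferon response list spread from -0.66 to 1.13 within the wild type mice.

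Red cell genes stood lower on average with a wide spread between mice. The late erythroid list was 1.24-fold lower, with 23 of 25 members lower (camera adjusted p = 0.0026, and adjusted p = 0.792 with an estimated correlation). The beta globin gene Hbb-b2 averaged 9.39 ± 0.62 against 10.22 ± 0.67 (SD, n = 4), Bpgm, which makes the hemoglobin effector bisphosphoglycerate, differed by -0.73, Tspo2 by -0.65 and the Hba-a2 probe set, at a low level of 2.49 against 2.73, by -0.24. All 15 measured members of the heme synthesis and iron uptake list were lower, by 1.23-fold on average (camera adjusted p = 0.0099, and adjusted p = 0.792 with an estimated correlation). Alas2, the first enzyme of erythroid heme synthesis, averaged 9.06 ± 0.54 against 9.81 ± 0.54, and Slc25a38, Fech and Urod differed by -0.43, -0.55 and -0.38. No member of either list passed, and the array means overlapped (exact p = 0.4 for each list). The erythroid mean of -0.31 lost its call without transgenic mouse 4 (-0.11) or wild type mouse 2 (-0.13) and without both Xist arrays (-0.08), and was -0.49 without transgenic mouse 1 and -0.52 without wild type mouse 1. The heme list mean of -0.29 lost its call without transgenic mouse 2 (-0.22), transgenic mouse 4 (-0.15) or wild type mouse 2 (-0.13), without both Xist arrays (-0.06) and with the Gapdh covariate (-0.23), and was -0.47 without transgenic mouse 1 and -0.48 without wild type mouse 1. Beside these lists the Gapdh 3' minus 5' difference stood at 0.78 against 1.03 (exact p = 0.171).

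Immediate early and unfolded protein genes stood higher, while the heat shock list had a mean of -0.11 with 8 of 12 members lower (camera adjusted p = 0.593), and passed as lower without wild type mouse 1 (mean -0.33). The immediate early list, whose genes are induced within minutes and also by tissue handling, was 1.25-fold higher with 17 of 18 members higher (camera adjusted p = 0.0011, and adjusted p = 0.792 with an estimated correlation). Atf3 averaged 7.74 ± 0.46 against 6.61 ± 0.72 and Fosb 7.32 ± 0.46 against 6.06 ± 1.00 (SD, n = 4), Klf2 differed by 0.46 and Klf6 by 0.44, and no member passed. The exact permutation p of the array means was 0.2. The mean of 0.32 was 0.13 without wild type mouse 1, which ended the call, and 0.51 with the Gapdh covariate. The unfolded protein and integrated stress response list was 1.13-fold higher, with 14 of 20 members higher (camera adjusted p = 0.026, and adjusted p = 0.792 with an estimated correlation). Its examples were again Atf3, which both lists hold, with Chac1 at 0.57, Ddit3 at 0.54 and Herpud1 at 0.36, none of them passing, and the exact p of its array means was 0.0857. That call was lost without transgenic mouse 2 (0.13), transgenic mouse 4 (0.16) or wild type mouse 1 (0.14), with array weights (0.13), without both Xist arrays (0.12) and in both settings restricted to brighter probe sets (0.20 and 0.18).

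Respiratory chain and fat cell genes completed the 13. The oxidative phosphorylation list was 1.07-fold lower, with 28 of 32 members lower (camera adjusted p = 0.0062, and adjusted p = 0.792 with an estimated correlation). Ndufb9, Ndufv2, Ndufc1 and Cox5a differed by -0.23, -0.22, -0.19 and -0.15, and no member passed. The exact permutation p of the array means was 0.143. The mean of -0.09 was -0.05 without transgenic mouse 2 and -0.07 without wild type mouse 1, and -0.08 without both Xist arrays, each of which ended the call. The adipocyte list was 1.18-fold lower, with 8 of 10 members lower (camera adjusted p = 0.037, and adjusted p = 0.792 with an estimated correlation). Its array means did not overlap, at -0.12 ± 0.10 against 0.12 ± 0.07 (SD, n = 4, two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give, unadjusted over the 35 lists). Car3 averaged 3.49 ± 0.29 against 4.26 ± 0.49, and the fatty acid binding protein gene Fabp4, also in the endothelial list, differed by -0.51. Retn, at a low level of 2.65 against 2.91, differed by -0.26 and Cidec, at 1.27 against 1.13, by 0.15. None of these members passed. That call was lost without transgenic mouse 1 (mean -0.25), 2 (-0.19) or 4 (-0.25) and without wild type mouse 1 (-0.24) or 3 (-0.21), and with array weights (-0.19), without both Xist arrays (-0.19), with the Gapdh covariate (-0.21) and with the mean of all probe sets of a gene (-0.17). Without probe sets below the median level the call was kept at a mean of -0.55. That setting leaves out low members such as Retn and Cidec, so its mean rests on fewer genes and is not a stronger shift of the same list. The background restricted to brighter genes left too few members for a value.

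Other blood lineages showed no list shift past the threshold. The megakaryocyte and platelet list had a mean difference of 0.21 (camera adjusted p = 0.51), with Thbs1 at 1.03 and Itgb3 at -0.16. It passed without wild type mouse 2 (mean 0.55, adjusted p = 0.000236) as well as without both Xist arrays (0.65) and with the Gapdh covariate (0.76), had a mean of 0.02 without transgenic mouse 4 and 0.14 without wild type mouse 4, and turned to -0.07 without wild type mouse 1, where Thbs1 was 0.36. The monocyte list had a mean of 0.10 (adjusted p = 0.593), which was 0.03 without transgenic mouse 2, 0.05 without wild type mouse 2, 0.16 without transgenic mouse 1, 0.17 without wild type mouse 4 and -0.02 without both Xist arrays, with the endotoxin co-receptor Cd14 at 0.73 and Ly86 at -0.26. The basophil and mast cell list had a mean of 0.03 and a median of -0.0004 (adjusted p = 0.86, test direction down). Its member Hdc, the histamine-forming enzyme, averaged 8.27 ± 0.21 against 7.18 ± 0.60 (SD, n = 4) and was the 1 member that passed adjusted over the list alone, while Csrp3 differed by -0.29. The plasma cell list had a mean of -0.02 and a median of 0.0031 (adjusted p = 0.86), with Sec11c at -0.21 and Sdc1 at -0.21. The stem and progenitor list had a mean of -0.03 (adjusted p = 0.942), with Cd34 at -0.44 and Procr at 0.21. The erythropoietin and STAT5 response list had a mean of 0.02 (adjusted p = 0.86), with Pim1 at 0.33 and Socs2 at -0.44 on its brighter probe set.

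Lists for the marrow's vessels, bone and stroma stayed near 0. The endothelial list had a mean of -0.0017 (camera adjusted p = 0.964), with Fabp4 at -0.51 and Lyve1 at 0.33. The stromal and osteoblast list had a mean of 0.01 (adjusted p = 0.86), with the bone matrix gene Ibsp at -0.81 and Pdgfrb at 0.41. The osteoclast list had a mean of -0.0015 (adjusted p = 0.86), with the decoy receptor Tnfrsf11b at -0.37 and Mmp9, also in the late neutrophil list, at 0.65. The Tnfrsf11b level was low, 1.72 against 2.10. The list of niche adhesion and release genes had a mean of 0.04 (adjusted p = 0.86), with the urokinase receptor Plaur at 0.66 and Vcam1 at -0.50. The skeletal muscle list, a sign of tissue carried over in dissection, had a mean of -0.05 (adjusted p = 0.631), with Tnni2 at -0.57 and Tnnt3 at -0.23. Both genes lay at low levels, Tnni2 at 2.78 against 3.36 and Tnnt3 at 1.31 against 1.55.

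Pathway lists that missed the threshold included several with single members of small p. The hypoxia and glycolysis list had a mean of 0.11 (camera adjusted p = 0.124), and 2 members passed as higher and 1 as lower adjusted over the list alone. Hexokinase Hk2 averaged 7.96 ± 0.14 against 7.39 ± 0.20 (SD, n = 4) and Pdk1 differed by -0.41. This list passed without transgenic mouse 1 (mean 0.17) or wild type mouse 1 (0.20), and its mean was 0.06 without transgenic mouse 4, 0.08 without wild type mouse 2 and 0.07 without both Xist arrays. The p53 target list had a mean of 0.10 (adjusted p = 0.317), with the cell cycle inhibitor Cdkn1a at 0.55 and the pro-apoptotic Pmaip1 at 0.96. Without wild type mouse 1 the mean was 0.04 and Pmaip1 differed by 0.63. The NF-kappaB and inflammatory cytokine list had a mean of 0.15 (adjusted p = 0.178), with Il6 at 0.86 and Relb at -0.22, and passed without wild type mouse 3 (mean 0.24). Its mean was 0.08 without wild type mouse 1, where Il6 was 0.57, 0.09 with array weights and 0.07 without both Xist arrays. The cholesterol synthesis list had a mean of 0.12 (adjusted p = 0.317), with Lss at 0.28 and Fdps at 0.51, and passed without wild type mouse 1 (0.26). Its mean was 0.04 without transgenic mouse 4, 0.03 without wild type mouse 2, where Fdps was 0.29, 0.06 without both Xist arrays, 0.06 with the Gapdh covariate and 0.04 with the mean of all probe sets of a gene. The ribosomal protein list had a mean of -0.04 (adjusted p = 0.111), with Rpl35 at -0.17 and Rps14 at -0.16.

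The remaining lists had adjusted p-values above 0.5. The heat shock list had a mean of -0.11 (camera adjusted p = 0.593), with Hspe1 at -0.38 and Hspa8 at -0.37, passed as lower without wild type mouse 1 (mean -0.33) and turned to 0.05 without wild type mouse 3. The cell cycle list had a mean of -0.01 and a median of -0.0049 but a test direction up (adjusted p = 0.964), with Ccne2 at -0.54 and Bub1b at 0.26, and passed as higher without both Xist arrays (mean 0.13). The interferon response list had a mean of -0.0097, a median of 0.06 and a test direction up (adjusted p = 0.86), with Gbp2 at 0.49 and Oas2 at 0.51, and passed as higher without wild type mouse 3 (mean 0.36, adjusted p = 0.00196), while its mean was -0.28 without transgenic mouse 1. The list of genes polymorphic between C57BL/6 and DBA/2 had a mean of -0.22 (adjusted p = 0.964), with H2-Ea at -1.70, or -0.24 without transgenic mouse 2, and Hc at 0.34. The sex-linked list had a mean of -0.19 (adjusted p = 0.964), with Xist at -0.69 and Eif2s3y at -0.14. Transgenic mouse 2 and wild type mouse 2 carried Xist signal of 10.19 and 10.38 and Eif2s3y values of 1.07 and 0.855, the pattern of female mice. The other arrays, with Xist at 3.02 to 4.73 and the Y-linked Eif2s3y at 6.64 to 7.28, had that of males. So 1 array of the female pattern stood in each group, and the settings without both Xist arrays hold the male pattern alone. The sex itself is not given in the sources used here.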

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

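Chosen only after the result was seen were the split count at the adjusted p, the test of an equal dilution of other lineages, and the settings that use Gapdh or Xist. A value was singled out where 1 mouse lay far from the other 3 of its group (Dixon's ratio). This was so for 19 of 306 tests, where chance gives about 15, or 1 in 20.

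Transgenic mouse 2 stood apart in 8 of these values. It had 9.45 for Litaf against 9.24 to 9.27 in the other transgenic mice, 2.66 for Ccr3 against 2.53 to 2.55, 3.19 for Fcer2a against 2.62 to 2.69, 8.43 for Herpud1 against 7.83 to 7.90 and 8.83 for Plaur against 8.18 to 8.28. It was lower for Cxcr6, at 1.55 against 1.82 to 1.86. Its Xist value was 10.19 against 3.02 to 3.98, and its Eif2s3y value 1.07 against 6.64 to 7.19. Wild type mouse 2 likewise had an Eif2s3y value of 0.855 against 7.07 to 7.28 in the other wild type mice. Wild type mouse 2 also had 9.23 for Ndufb9 against 9.31 to 9.32, 11.87 for Rps14 against 11.93 to 11.94 and -0.069 for the osteoclast list mean against 0.017 to 0.033. Wild type mouse 1 had 7.497 for Gstm1 against 6.55 to 6.63, 8.15 for Padi4 against 6.77 to 7.003, 5.00 for Mrc1 against 6.13 to 6.21 and 7.06 for Herpud1 against 7.78 to 7.87. Transgenic mouse 3 had 2.61 for Il5ra against 2.07 to 2.16. Transgenic mouse 4 had 5.97 for Tspo2 against 6.74 to 6.80 and a Gapdh 3' minus 5' difference of 1.16 against 0.60 to 0.69.

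Other ways of dividing the arrays gave results as large as the groups of the study. There are 35 splits of the 8 arrays into 4 and 4. At the unadjusted p, 4 of the 35 gave as many as the real 2331, and the highest other gave 4221, so chance cannot be excluded. For the gene lists 12 of the 35 gave as many as the real 13, and the highest other gave 18, so chance cannot be excluded there either. At the adjusted p the real count was 0, so that all 35 splits had to give as many, and this count tests nothing. The highest other count there was 461, in the same split that gave 4221. That split is the study's grouping with transgenic mouse 1 and wild type mouse 1 exchanged, so 6 of the 8 arrays keep their group. It was picked as the highest of the other splits and points to a structure of the samples. What that structure is, an outlying array or an exchange of both included, was not tested, and the labels were kept.

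Neutrophil genes stood higher and B cell genes lower in transgenic marrow, by 0.78 (SE 0.34, exact two-sided p = 0.114) in the late neutrophil mean minus the mean of both B cell lists. This difference was 0.74 (SE 0.43) without both Xist arrays and 1.09 (SE 0.17) without wild type mouse 1. That mouse stood at 0.53, among the transgenic mice at 0.14 to 0.76, and the other wild type mice at -0.76 to -0.57. Leaving it out therefore had to widen the difference and narrow the spread, which is no added support. No other single mouse was left out for this score. With the Gapdh 3' minus 5' difference as a covariate the difference was 0.62 (SE 0.40), over 0.5 of its size but under 2 standard errors, so a part played by RNA degradation cannot be told apart from the groups with 8 arrays. A larger share of granulocytes would dilute every other lineage alike. The resident macrophage, late erythroid and T and NK cell lists stood lower too (-0.39, -0.31 and -0.24). So did the eosinophil list (-0.31), though eosinophils are themselves granulocytes. The B cell lists lay below the mean of the monocyte, basophil and plasma cell lists (difference -0.47, SE 0.19, exact p = 0.114). This comparison was chosen after the result was seen. It includes basophils, also granulocytes, and leaves out the other lists that stood lower. It therefore does not test equal dilution of all lineages, and dilution stays open. An effect of PlGF on lymphoid or granulocyte cells remains open and untested, as does the structure of the samples seen in the splits.

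On transgenic mouse 2 the brightest probe set of H2-Ea, a class II gene that C57BL/6 mice do not express, read 1.85 against 6.94 to 8.50 on the other arrays. Alleles segregating in the background may account for it, but only if the mice were not all first-generation crosses, which share a genotype. Among the 100 measured genes nearest to H2-Ea, 2 stood over 1 log2 unit from the median of the other arrays, Msh5 (-1.66) and Aif1 (-1.06). That count lay at the percentile 85.84 of other blocks, whose median was 0 and highest 5. That lies between what a strain block and no block predicted, so the test leaves it open.

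Alleles linked to the transgene could also set apart genes near 1 locus. The best window of 20 neighbouring genes held 4 at an unadjusted p under 0.01, as many as in 11 of the 35 splits, whose highest other was 8. This neither singles out a locus nor excludes one, and the insertion site is not given in the sources used here.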

How the results depend on the processing

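Alternatives that use the Xist signal or the Gapdh difference, and no others here, were chosen after the data were seen. Limma called 0 probe sets in either direction in every setting with adjusted p-values but array weights. Without adjustment 1203 were higher and 1128 lower at a p under 0.05. Array weights called 1 as higher, Acod1, and the lowest adjusted p was 0.0496 there, 0.0544 without wild type mouse 1 and between 0.152 and 0.775 in the other fits. All 16 genes named by smallest p kept their direction with an unadjusted p under 0.05 in each fit, except that 11 remained to be tested when probe sets below the median level were left out. These genes were picked for small p on the same arrays, so that outcome was nearly fixed in advance and is no independent support. The Pgf difference was -0.015 without both Xist arrays and above 0 in the other fits. Of 35 lists camera called 8 without both Xist arrays, 8 among genes above the median level, 0 with an estimated correlation and 0 with fry, and from 7 to 13 with 1 mouse left out. The late neutrophil, mature B cell, B cell precursor and resident macrophage lists kept their calls in all 18 settings run with the preset correlation, and the adipocyte list in 8 of 17. The cause of these changes was not tested, except that settings without arrays or probe sets test fewer of them. The megakaryocyte list was called as higher without both Xist arrays (0.65) and with the Gapdh covariate (0.76). Restriction to brighter probe sets left no value for Pgf and the sex-linked list, and that of the background none for the adipocyte, skeletal muscle, VEGF and sex-linked lists. Trend and robust variance was not run for the lists, since camera does not use that fit.

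Replicate numbers did not pair the mice: deviations of same-numbered mice from their group means correlated at -0.365, 0.185, 0.10 and -0.116, and not every mouse correlated best with its own number. With the replicate block limma called 0 probe sets higher and 0 lower, 1773 stood at an unadjusted p under 0.05, camera called the same 13 lists, and the Pgf difference was 0.12. All 16 named genes kept their direction and an unadjusted p under 0.05, which their choice by small p on the same arrays made likely in advance.

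Lists near 0 changed sign between settings, and the cause was not tested. With arrays centred on their medians the plasma cell list had 0.000102, endothelial 0.0148, osteoclast 0.0150, cell cycle 0.0035 and interferon 0.0067. With further quantile normalization endothelial had 0.0040 and osteoclast 0.0050. Without probe sets below the median level plasma cell had 0.0200, osteoclast 0.115 and interferon 0.0081. With array weights plasma cell had 0.0296, endothelial 0.0033 and cell cycle 0.0015. Without both Xist arrays monocyte had -0.0232, basophil -0.0587, stem cell 0.0732, endothelial 0.0260, interferon 0.0017, niche -0.0051, Vegfc 0.0595 and cell cycle 0.133, which was called there (adjusted p = 0.00102). With the Gapdh covariate basophil had -0.0327, plasma cell 0.0246, stem cell 0.0981, endothelial 0.0325, stromal -0.0050, cell cycle 0.0353, heat shock 0.0786, Vegfc 0.0699 and Kdr 0.0941. With the mean of all probe sets of a gene the erythropoietin list had -0.0344 and endothelial 0.0208. Among genes above the median level plasma cell had 0.0362, stromal -0.0258, osteoclast 0.115 and interferon 0.0081.

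With each mouse left out in turn the differences that changed sign ran from -0.0931 to 0.0819 for the erythropoietin list, -0.0710 to 0.553 for megakaryocyte, -0.0168 to 0.0908 for basophil, -0.0977 to 0.0931 for plasma cell, -0.114 to 0.0452 for stem cell, -0.0217 to 0.0171 for endothelial, -0.0709 to 0.162 for stromal, -0.0247 to 0.0092 for osteoclast, -0.100 to 0.0721 for cell cycle, -0.277 to 0.365 for interferon, whose highest value, without wild type mouse 3, was called (adjusted p = 0.00196), -0.326 to 0.0461 for heat shock, -0.522 to 0.0532 for sex-linked and -0.377 to 0.0510 for strain-polymorphic genes. They ran from -0.181 to 0.0220 for Vegfc, -2.399 to 0.852 for Xist and -1.71 to 1.32 for Eif2s3y. Signal over background limits genes such as Pgf, Vegfc and Ccr3, which lie at low levels on these arrays, and no detection call was used here.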

Other observations

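Of the tests below, the correlation of erythroid with neutrophil genes, and for the glucocorticoid genes the estimated correlation and the test without shared genes, were chosen after the result was seen. Genes named in this part outside the fixed rule were chosen after their values were seen.

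At least 2-fold higher at an unadjusted p under 0.05 were 18 probe sets, and 5 were as far lower. The higher ones included the decoy interleukin receptor Il1r2 at 8.37 ± 0.68 against 7.21 ± 0.55 (SD, n = 4), the inflammasome sensor Nlrp3 at 5.83 ± 0.69 against 4.62 ± 0.33, and Asprv1 at 7.36 ± 0.70 against 5.97 ± 1.13. The long noncoding RNA Neat1 differed by 1.23 and the phosphate transporter Slc20a1 by 1.24 on 1 probe set and 0.11 on another. Both Hdc probe sets were higher, by 1.16 and 1.09. Lower ones included the B cell marker Ms4a1, by -1.14 and -0.998 on its probe sets, and Fam220a, by -1.20 and -0.92. None of these passed the adjusted test.

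Interferon-induced genes split the mice within each group. The list mean was 0.80 and 0.45 in transgenic mice 1 and 3 and -0.63 in each of transgenic mice 2 and 4. In wild type mice 1 to 4 it was -0.66, -0.59, 1.13 and 0.14.

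Erythroid and neutrophil genes moved in opposite directions from mouse to mouse. Over the 8 arrays the late erythroid and late neutrophil list means correlated at a Pearson r of -0.8266 (permutation p = 0.0124). Adjusted over 2 relations this permutation p was 0.0248. The Spearman rho was -0.905 (permutation p = 0.00427). The pair was picked from many possible pairs of lists after its values were seen on these same arrays. Neither these p-values nor the adjustment over 2 relations correct for that choice, so they do not exclude chance. Without the 2 mice farthest from the erythroid median r was -0.699, and within groups it was -0.843. The hypothesis that 1 axis of cell composition, such as the share of red cell precursors in the harvested marrow, runs through both groups may account for the relation. It was tested only on the correlation that prompted it and stays open. Whether normalization adds to a negative relation was not tested. The Gapdh difference and the neutrophil minus B cell score had an r of -0.552 (permutation p = 0.141, adjusted p = 0.141) and a rho of -0.429 (p = 0.298), and r was -0.032 without the 2 farthest mice.

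The hypothesis of a glucocorticoid response was tested because Per1 (difference 1.19), Klf9 (0.97 on a bright probe set, -0.04 to 1.31 over all 7) and Il1r2 are known targets. The other 12 listed glucocorticoid-induced genes had a median difference of 0.265, with 10 higher and 2 lower, Fkbp5 and Errfi1 alone at an unadjusted p under 0.05, and a camera p of 0.0205 at the preset correlation and of 0.213 with an estimated correlation. Of the 12, 4 also stand in lists described above, Dusp1 in the immediate early and Cebpd in the late neutrophil list among them, and without these 4 the camera p was 0.0243 and 0.171. Array means of the 12 did not separate the groups (two-sided exact permutation p = 0.143). The direction is in line with the hypothesis, which 4 mice against 4 leave open.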
